A study of Mus musculus with 482 samples.

How the data were processed

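Hearts of 482 Diversity Outbred mice on a diet with 45% fat were pulverized frozen, and RNA was isolated with magnetic beads, per the labels' protocols. Each library was made from 100 ng of total RNA with a kit that selects polyadenylated RNA, after 2 ul of spike-in RNA diluted 1000 times had been added. The values used here held 0 spike-in transcripts. The authors deposited estimated counts per gene, of which 20.9% were not whole numbers at a tolerance of 1e-06. Reads may have been shared between genes or transcripts, which was not tested. The quantifier, the gene annotation and any use of strand were not given in the sources used here. GRCm38 was the genome build named in the submitters' processing notes. The table held 20618 genes, and every gene had a count of at least 1 in at least 50% of the libraries, so genes had been filtered before deposit. Of the gene identifiers 20610 were found in GENCODE M21 on the same chromosome, and 19943 of them had the same start and end. Spreadsheet software had turned 22 gene symbols into dates, and those genes were not named. The authors also deposited log2 values, made with a variance-stabilizing transformation to judge by their name, with DESeq2 named in the submitters' processing notes. These log2 values correlated at 1.00 (0.999656 before rounding) with values recomputed from the counts, and the 2 were not identical, for a reason that was not tested. Their lowest value was 5.82, and sex differences on them correlated at 0.866 with the log2 fold changes of the edgeR fit. Differences on the deposited values are thus on another scale, and their sizes are not log2 fold changes of the counts. Deposited gene coordinates were in megabases and are given here in bases.

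Sex came from the sample titles, which gave 239 females and 243 males, and the animal and library numbers in the titles gave 5 animal blocks and 2 library series. These groupings, the tests, the rule for named genes, the gene lists and most alternatives were fixed before the data were examined. Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr by sex, a quasi-likelihood F test on animal block, library series and sex), limma 3.58.1 and DESeq2 1.42.0. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and 16710 genes were tested, 16171 of them autosomal. Log2 CPM values used a prior count of 2. Sex by block interaction and block were tested with 4 degrees of freedom each. Spread between animals was the residual SD of log2 CPM after sex, block and series, and its difference between sexes was tested with limma on absolute deviations from the median of each sex and block. Lists were tested with limma's camera with an estimated correlation, and with fry. Relations across animals used residuals of log2 CPM and 100000 permutations. Total counts ranged from 34.3 to 141.02 M per library, and a count of 0 in a female library of median depth allowed up to 0.0552 CPM, taking 3 counts as the floor and covering counting error only.

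Named genes were the members of the escape and Y-linked lists past the test with 3 further X-linked genes, the 12 autosomal genes with the largest change in each direction among those with a mean log2 CPM of at least 1 and the same sign in all 5 blocks, and up to 4 members of each list with the smallest p, with members going against a list only if the list passed, which 0 lists did. To these were added the 5 genes with the smallest p for interaction, for block and for spread in each direction, the 20 autosomal genes with the widest spread, the member of each list with the widest spread and the genes of the relations. Symbols made of Gm and a number, or ending in Rik, were counted and not named. Some genes chosen by these rules are not reported here. Myh6, Myh7 and Nppb, which belong to the relations, were named by that rule among the sarcomere and stress genes.

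The 37 gene lists covered X-linked escape genes, Y-linked genes, sarcomere, cardiac stress and fetal genes, calcium handling and ion channels, fatty acid oxidation, PPAR-alpha targets, glucose uptake and glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, branched-chain amino acid and ketone use, cholesterol synthesis, glucocorticoid targets, core clock and clock outputs, immediate early and heat shock genes, interferon response, integrated stress response, extracellular matrix, sex hormone receptors and steroid enzymes, and the cell cycle. Marker lists covered fibroblast, endothelial, smooth muscle and pericyte, macrophage, T and NK cell, B and plasma cell, neutrophil, erythroid, adipocyte, brown adipocyte, atrial cardiomyocyte, skeletal muscle, thymocyte, mesothelial, lung epithelium, Schwann and neuronal, and hepatocyte genes. The sex-linked lists were described and not tested as sets, and 2 lists had fewer than 3 tested members.

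The tests of sex, interaction, spread and lists were run on simulated data of 16710 genes with the real library sizes, and the tests of block and series, the fits of single blocks and the relations were not. For the sex difference 38 of 50 genes changed by 1.1-fold were called, 49 of 50 changed by 1.25-fold, 49 of 50 by 1.5-fold and 50 of 50 by 2-fold, with 6 calls among 16510 unchanged genes. With no interaction simulated 0 genes were called. For spread 198 of 200 genes widened by 1.5 times in females were called and 12 of 16510 unchanged genes. A list of 20 genes changed by 1.1-fold was called and 0 of 100 random lists were. In the simulation genes varied independently of each other. The real lists had estimated correlations between genes from 0.028 (sex hormone receptors and steroid enzymes) to 0.72 (B and plasma cell). The run with lists thus does not show the power to call a real list. No 2 libraries held identical counts, and the closest pair, animals 62 and 31, had a chi-square of 187.7 per degree of freedom, far above sampling noise.

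The alternatives were DESeq2's size factors, DESeq2's Wald test, limma-voom, limma on the deposited log2 values, no filter beyond 1 count, a stricter filter of at least 1 CPM in at least 50% of libraries (12816 genes), sex alone, block alone, covariates for 5 marker means (adipocyte, skeletal muscle, thymocyte, atrial cardiomyocyte and erythroid) and leaving out the 2 female libraries with Xist at the male level. Prior count 0.5 was tried for spread and a preset correlation of 0.01 for lists. Leaving out 18 libraries whose thymocyte score lay more than 5 median absolute deviations above the median of their sex, leaving out 6 libraries as far above it in skeletal muscle, erythroid, neutrophil or hepatocyte markers, together or one at a time, and a linear trend on animal number within each block, were chosen after seeing the data. Other splits of the samples, with sex drawn over all libraries or within a single block and blocks drawn within each sex, numbered 100 per result, the real one included, and were refitted with limma on log2 CPM.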

Results

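Heart transcriptomes were measured by sequencing of polyadenylated RNA in Diversity Outbred mice, a population of genetically unlike animals bred from several inbred founder strains. All animals ate a diet rich in fat and sugar, with 45% fat by the labels. Female and male libraries, each from a separate animal, formed the only groups that the labels named. Total estimated counts ranged from 34.3 to 141.02 M per library, with a median of 55.2 M, and averaged 57.5 ± 14.2 M in females and 59.7 ± 15.3 M in males (SD). Animal numbers fell into 5 blocks, each with 46 to 50 females and 47 to 50 males, most of them with females numbered before males, and library numbers into 2 series. Both were entered in the fits over all libraries, save for alternatives that left them out, since animals or libraries of a block can share a batch. Mitochondrially encoded genes took 20.3 ± 2.31% of counts in females and 21.4 ± 2.34% in males (SD).

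Genes of the sex chromosomes showed the widest gap between female and male hearts. Xist, the noncoding RNA that coats the inactive X chromosome (ENSMUSG00000086503, chromosome X, 103460366 to 103483254 on GRCm38), averaged 351.1 ± 66.7 CPM in females and 1.32 ± 0.909 CPM in males (SD). All 15 listed X-linked genes known to escape X inactivation were higher in females, with a median log2 fold change of 0.59. The histone demethylase gene Kdm6a (ENSMUSG00000037369, chromosome X, 18162575 to 18279936 on GRCm38) was higher by 0.92 ± 0.015 on the log2 scale (SE), Eif2s3x by 0.66 ± 0.013 and Kdm5c by 0.63 ± 0.011. The smallest differences among the escape genes were those of Shroom4 (0.11 ± 0.020) and Bgn (0.18 ± 0.017). The 4 listed Y-linked genes in the table had 0 counts in every female library. Whether counting made use of the labelled sex was not given in the sources used here. In males Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629 on GRCm38) averaged 78.9 ± 7.39 CPM, Eif2s3y 44.6 ± 4.10 CPM, Uty 25.5 ± 2.64 CPM and Kdm5d 19.5 ± 2.11 CPM (SD). Against a floor of 3 counts in a female library of median depth, the male means were at least 1430-fold higher for Ddx3y and 807-fold for Eif2s3y, with the floor covering counting error only. Xist lay at the male level, at 3.18 and 0.854 CPM, in 2 female libraries, those of animals DO153 and DO347. Among further X-linked genes the largest differences were those of Tsix (1.03 ± 0.099), Atp2b3 (−0.67 ± 0.11) and P2ry10 (0.62 ± 0.14). P2ry10 was higher in females by 2.39 in block 1 and lay at −0.61 in block 3. It did not pass with marker means of 5 cell types as covariates (0.15). Atp2b3 lost its call (−0.54) with a linear trend on animal number within each block, an alternative chosen after seeing the data. This trend overlaps with sex because most blocks number females before males, and the SEs were 1.96 times as large at the median. A call lost with it thus need not mean a smaller difference. Tsix overlaps Xist on the opposite strand and no source used here states whether counting used strand, so its difference is uncertain. In edgeR's quasi-likelihood test 52.9% of the X-linked genes passed, 94 of them higher in males.

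**Figure D1:**
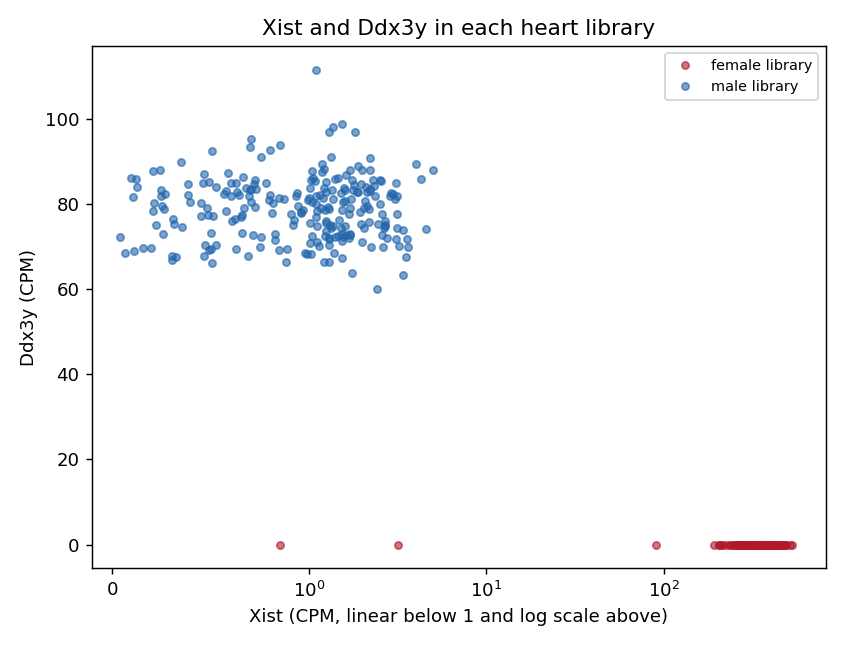
Xist (horizontal axis, CPM, linear below 1 and logarithmic above) against Ddx3y (vertical axis, CPM) in each heart library, with females in red and males in blue. Ddx3y was 0 in all females, and 2 of them had Xist at 3.18 and 0.854 CPM.

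Female hearts had more RNA from Col14a1, a collagen of the fibril surface, and male hearts more from C7, a component of the complement membrane attack complex. Col14a1 (ENSMUSG00000022371, chromosome 15, 55307750 to 55520803 on GRCm38) averaged 33.7 ± 6.81 CPM in females and 18.8 ± 4.38 CPM in males (SD), a log2 fold change of 0.85 ± 0.029 (SE). C7 (ENSMUSG00000079105, chromosome 15, 4988762 to 5063740 on GRCm38) averaged 3.004 ± 1.44 CPM in females and 13.9 ± 7.84 CPM in males, a log2 fold change of −2.21 ± 0.065. Among autosomal genes with a mean log2 CPM of at least 1 and the same sign in all 5 blocks, the largest difference in favour of females was that of Cfd, the complement factor that adipocytes secrete as adipsin (ENSMUSG00000061780, chromosome 10, 79890853 to 79892655 on GRCm38), at 1.33 ± 0.16. Other genes higher in females were Adamtsl2 (0.74 ± 0.042), Igfbp3, which binds insulin-like growth factors (0.61 ± 0.035), Thy1 (0.56 ± 0.062), Lsamp (0.55 ± 0.053) and Kcne1, a potassium channel subunit (0.54 ± 0.075). Also higher in females were Elovl6 (0.77 ± 0.12), Car3 (0.67 ± 0.12), Cyp2e1 (0.62 ± 0.13), Pck1 (0.55 ± 0.13) and Fasn (0.54 ± 0.11). Of 10 adipocyte markers 7 were higher too, with a median log2 fold change of 0.33 over the list, which did not pass against other genes (adjusted p = 0.681 in limma's camera). When marker means of 5 cell types, adipocytes among them, were entered as covariates, Pck1 lay at −0.013, Car3 at 0.062, Cyp2e1 at 0.026 and Fasn at 0.12, none of them past the threshold. With the trend on animal number Elovl6 (0.20), Kcne1 (0.23), Car3 (0.57), Pck1 (0.42), Fasn (0.051), and of the genes below Inmt (−0.35) and Cxcl14 (−0.32), lost their calls. Hsd11b1, which regenerates active glucocorticoid (ENSMUSG00000016194, chromosome 1, 193221634 to 193264075 on GRCm38), was lower in females (−0.89 ± 0.032), as were Lvrn (−0.77 ± 0.065), the opioid precursor gene Penk (−0.74 ± 0.054), Lgi1 (−0.59 ± 0.060) and the angiotensin-converting enzyme gene Ace (−0.50 ± 0.035). The other genes among the 12 with the largest differences in favour of males under the same bounds were Hspa1a (−0.70 ± 0.12), Hspa1b (−0.69 ± 0.13), Atp2b2 (−0.64 ± 0.088), Tmem150c (−0.64 ± 0.085), Inmt (−0.54 ± 0.090) and Cxcl14 (−0.50 ± 0.077). Hspa1a and Hspa1b are near-identical copies, so the share of reads given to each is uncertain.

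With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 3906 genes were higher in females and 3393 in males, of 16710 tested. Most differences were small, with a median of 1.06-fold among the 7005 called autosomal genes, and only 66 genes in females and 44 in males reached 1.5-fold. Of the called autosomal genes, 4697 (67.1%) had the same sign in all 5 animal blocks fitted alone, which were part of the data that called them. With the trend on animal number, where the SEs were 1.96 times as large at the median, the counts fell to 1170 and 1328. As a percentage of the 16710 genes, those of at least 1.5-fold ranged from 0.0598% to 0.880% in females and from 0.0658% to 0.383% in males over the alternative settings. The lowest value of each sex came from the deposited log2 values, which are on another scale.

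**Figure D2:**
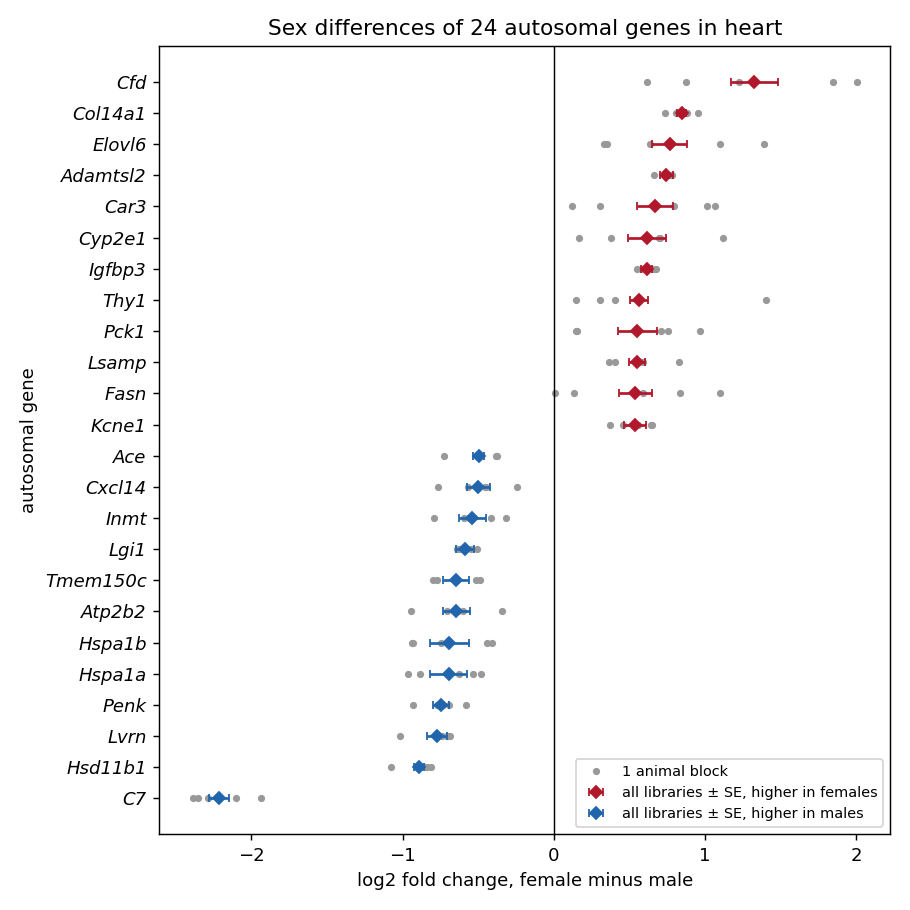
Log2 fold change, female minus male (horizontal axis), of the 12 autosomal genes with the largest difference in each direction (vertical axis), among those with a mean log2 CPM of at least 1 and the same sign in all 5 blocks. Diamonds give the fit over all libraries with its SE, and gray points the 5 animal blocks fitted alone, from −2.21 for C7 to 1.33 for Cfd.

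Many single genes of mitochondrial energy metabolism were lower in females by small margins, though none of their lists passed against other genes with an estimated correlation (adjusted p of limma's camera 0.359 for fatty acid oxidation and mitochondrially encoded genes and 0.425 for nuclear-encoded oxidative phosphorylation). Of 24 fatty acid oxidation genes 21 were lower in females and 1 higher, with Acadm (−0.15 ± 0.017), Slc25a20 (−0.14 ± 0.017), Acads (−0.14 ± 0.017) and the fatty acid transporter gene Cd36 (−0.10 ± 0.012) the clearest by p. Of 32 nuclear-encoded oxidative phosphorylation genes 25 were lower in females and 0 higher, among them Ndufa10 (−0.10 ± 0.010) and Ndufa9 (−0.082 ± 0.0095). Of 13 mitochondrially encoded genes 11 were lower in females, among them mt-Co1 (−0.14 ± 0.016), mt-Nd1 (−0.16 ± 0.023) and mt-Nd4 (−0.15 ± 0.022). Of 15 genes of branched-chain amino acid and ketone use 12 were lower in females, the clearest by p being Bckdha, a subunit of the branched-chain ketoacid dehydrogenase (−0.22 ± 0.018), with Ivd (−0.14 ± 0.017) and Acat1 (−0.12 ± 0.014). Of 22 genes of glucose uptake and glycolysis 12 were lower in females and 3 higher, with Pgam2 (−0.18 ± 0.016) and Pkm (−0.095 ± 0.014) among the lower. PPAR-alpha targets went both ways, with 4 of 16 higher in females, including Ucp3 (0.25 ± 0.064) and Vnn1 (0.46 ± 0.081), and 4 lower, including Ech1 (−0.097 ± 0.019) and Mlycd (−0.060 ± 0.019). Among 20 cholesterol synthesis genes 3 were higher in females, including Lss (0.20 ± 0.061) and Sqle (0.13 ± 0.050), and 2 lower, namely Fdft1 (−0.075 ± 0.019) and Hmgcs1 (−0.051 ± 0.014). Sqle lay at −0.017 with the trend on animal number and at 0.046, not past the threshold, with the marker covariates. Slc25a20 (−0.080), Cd36 (−0.050), Mlycd (−0.0055), mt-Nd4 (−0.11) and Fdft1 (−0.095) also lost their calls with the trend.

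Of 13 genes of cardiac stress 7 were lower in female hearts, 1 was higher and 5 did not pass, and the list did not pass against other genes (adjusted p = 0.425 in limma's camera). Among the lower were Acta1, the skeletal alpha-actin of the fetal heart (−0.47 ± 0.095), Ankrd1 (−0.37 ± 0.044), Xirp2 (−0.24 ± 0.025) and Myl4 (−0.19 ± 0.043). The natriuretic peptide gene Nppa differed by −0.041 ± 0.044 and did not pass, whereas Nppb passed at −0.27 ± 0.066. Of 20 sarcomere genes 10 were lower in females and 2 higher. Myl3 (−0.11 ± 0.014), Tpm1 (−0.11 ± 0.018) and Ldb3 (−0.073 ± 0.011) were lower, Myh7 fell by 0.28 ± 0.089, and Myh6, the main adult myosin heavy chain gene, was higher by 0.094 ± 0.016. Of 16 immediate early and heat shock genes 8 were lower in females and 0 higher, with Hsp90aa1 at −0.20 ± 0.041 and Hspb1 at −0.17 ± 0.036. Of 22 calcium handling and ion channel genes 5 were lower, including Camk2d (−0.088 ± 0.013) and Hcn4 (−0.18 ± 0.048), and 2 were higher. Glucocorticoid targets were higher in females in 8 of 14 cases, the clearest by p being Klf9 (0.17 ± 0.022) and Tsc22d3 (0.19 ± 0.031), and lower in 0. Sex hormone receptors and steroid enzymes split, with 5 of 11 higher, including the estrogen receptor gene Esr1 (0.40 ± 0.053), and 4 lower, including Hsd17b4 (−0.090 ± 0.013). Interferon response genes were higher in 5 of 22 cases, such as Ddx58 (0.11 ± 0.028) and Stat2 (0.14 ± 0.037). Of 15 integrated stress response genes Chac1 (0.25 ± 0.058) and Pck2 (0.10 ± 0.024) were higher and Ddit3 (−0.15 ± 0.030) and Atf4 (−0.077 ± 0.019) lower. Of 18 clock genes and outputs 2 were higher, including Npas2 (0.17 ± 0.042), and 4 lower, including Bhlhe41 (−0.21 ± 0.033). Arntl (0.053 ± 0.046) and Dbp (0.0070 ± 0.12) did not pass. The trend on animal number ended the calls of Acta1 (−0.38), Nppb (−0.29), Tpm1 (−0.082), Ldb3 (−0.055), Myh7 (−0.13), Myh6 (0.083), Hsp90aa1 (−0.18), Hspb1 (−0.16) and Hcn4 (−0.21). It also ended those of Ddx58 (0.15), Stat2 (0.14), Chac1 (0.29), Pck2 (0.059), Ddit3 (−0.14), Atf4 (−0.067) and Npas2 (0.077). Some of these differences, such as those of Nppb and Chac1, were no smaller with the trend, which widened the SEs. Others, such as those of Myh7 and Npas2, were smaller.

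Of 10 fibroblast markers 8 were higher in female hearts, though the list did not pass against other genes (adjusted p = 0.134 in limma's camera). The clearest by p were Lum (0.41 ± 0.028), Mfap5 (0.38 ± 0.026) and Pdgfra (0.18 ± 0.018), and Dpep1 was lower (−0.35 ± 0.028). Of 24 extracellular matrix genes 14 were higher, 8 did not pass and 2 were lower, and this list did not pass either (adjusted p = 0.425 in limma's camera). The higher ones included Col6a3 (0.31 ± 0.026), Col6a2 (0.21 ± 0.022) and Col6a1 (0.21 ± 0.023). Of 10 adipocyte markers 7 were higher in females, including the resistin gene Retn (ENSMUSG00000012705, chromosome 8, 3655770 to 3660110 on GRCm38) at 1.55 ± 0.14, Adipoq (0.62 ± 0.12) and Lipe (0.14 ± 0.027), whereas Lep, the leptin gene, was lower (−0.66 ± 0.17). Adipoq lay at −0.0058 with the marker covariates. Of 8 brown adipocyte genes 2 were higher, Dio2 (0.39 ± 0.053) and Elovl3 (0.51 ± 0.20), and 2 lower, Cpt1b (−0.076 ± 0.011) and Ppara (−0.056 ± 0.020). Elovl3 lay at −0.27 with the marker covariates. On the deposited log2 values, where sizes are on another scale, it lay at 0.077, not past the threshold. Ppara lay at −0.036, not past the threshold, with the marker covariates. Col6a1 (0.10), Adipoq (0.38), Elovl3 (−0.19), Cpt1b (−0.036) and Ppara (−0.026) lost their calls with the trend on animal number.

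All 10 B and plasma cell markers passed as higher in females, among them Ms4a1 (0.69 ± 0.16), Cd79a (0.58 ± 0.14) and Mzb1 (0.35 ± 0.076), as did 4 of 5 T and NK cell markers, among them Il7r (0.67 ± 0.10) and Cd2 (0.55 ± 0.14), though neither list passed against other genes (adjusted p of limma's camera 0.791 and 0.459). With the marker covariates Ms4a1 lay at 0.071, Cd79a at 0.011, Cd79b at 0.023, Mzb1 at 0.11 and Cd2 at 0.086, none of them past the threshold. Of 10 listed thymocyte markers only 3 were tested, of which Cd4 was higher (0.51 ± 0.17), and Tcf7 (0.11 ± 0.21) and Arpp21 (0.21 ± 0.12) did not pass. The thymocyte score of a library is the mean of these 3 genes. Tcf7 passed with sex alone (1.85) and in limma-voom (0.46) and lay at −0.25 with the trend on animal number. Arpp21 passed with sex alone (0.55) and lay at −0.15 with the marker covariates, −0.13 without the libraries rich in thymocyte markers and −0.045 with the trend. Of 16 cell cycle genes 6 were higher, including Mki67 (0.35 ± 0.092), Top2a (0.31 ± 0.10), Kif11 (0.25 ± 0.083) and Pcna (0.082 ± 0.014). Without 18 libraries rich in thymocyte markers, 10 of them block 1 females, left out after seeing the data, Top2a lay at −0.025, Kif11 at −0.0027, Mki67 at 0.075 and Cd3e at 0.13, none of them past the threshold, whereas Cd2, Il7r, Cd4, Ms4a1 and Pcna stayed past it. On the deposited log2 values, where sizes are on another scale, Top2a (0.071), Kif11 (0.057) and Mki67 (0.10) did not pass either. Of 12 macrophage markers 4 were higher, such as C1qa (0.11 ± 0.031) and Lyve1 (0.12 ± 0.034), and of 3 neutrophil markers Mmp9 was higher (0.32 ± 0.10) but lost its call with the marker covariates (0.20) and with the trend on animal number (0.099). The trend also ended the calls of Cd2 (0.64), Cd4 (0.27), Mki67 (0.34), Top2a (0.17), Kif11 (0.21) and Pcna (0.049). Of 7 erythroid genes Slc4a1 was higher (0.46 ± 0.20, adjusted p = 0.0465 in edgeR's test), from −1.22 in block 1 to 3.28 in block 5, and lost its call in 7 of the other settings, with −0.015 in limma-voom and 0.022 on the deposited log2 values. Without the library of female DO497 of block 5, which stood apart in erythroid and neutrophil markers, Slc4a1 lay at 0.20 over all blocks and 1.67 in block 5 and did not pass, and it just lost its call without the library of female DO64 or of female DO335. Among the others Hbb-bs lay at −0.10 ± 0.080, Hba-a2 at −0.11 ± 0.13 and Alas2 at −0.059 ± 0.094, none of them past the threshold. They passed in limma-voom (−0.26, −0.47 and −0.26) and on the deposited log2 values (−0.25, −0.41 and −0.20), and lay above 0 with the trend on animal number (0.27, 0.31 and 0.40). Without the library of female DO497 Hbb-bs (−0.20) and Alas2 (−0.20) passed and Hba-a2 (−0.22) did not. The hemoglobin genes have near-identical copies and their single values are uncertain.

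Markers of the vessel wall differed little. Of 10 endothelial markers Tek was higher in females (0.047 ± 0.013) and 3 were lower, namely Kdr (−0.087 ± 0.023), Cldn5 (−0.13 ± 0.039) and Tie1 (−0.036 ± 0.015). Of 10 smooth muscle and pericyte markers 3 were higher, Pdgfrb (0.073 ± 0.017), Notch3 (0.043 ± 0.015) and Acta2 (0.15 ± 0.064), of which Acta2 (adjusted p = 0.0494 in edgeR's test) lost its call in 8 of the other settings at about the same size. Tie1 lost its call in 5. Of 10 atrial cardiomyocyte markers 3 were lower in females, Myl4 (−0.19 ± 0.043), Sln (−0.13 ± 0.041) and Stard10 (−0.12 ± 0.030). Of 6 skeletal muscle markers Tnnt3 (0.87 ± 0.14), Mylpf (0.54 ± 0.13) and Tnni2 (0.41 ± 0.099) were higher, and with the marker covariates, which include this list, Tnnt3 (0.20) and Mylpf (0.082) did not pass. Without the library of female DO503, the highest in this list, they lay at 0.45, 0.27 and 0.25 and passed. Without 6 libraries that stood apart in skeletal muscle, erythroid, neutrophil or hepatocyte markers, left out after seeing the data, Tnnt3 passed at 0.29, and Mylpf (0.21) and Tnni2 (0.19) did not. Of 8 mesothelial markers Lrrn4 (0.13 ± 0.048) and Msln (0.10 ± 0.038) were higher, but not past the threshold with the marker covariates (0.010 and 0.046). Of 7 Schwann and neuronal markers 2 were higher, and 2, S100b (−0.27 ± 0.088) and Dbh (−0.17 ± 0.060), were lower. Both tested hepatocyte markers, Ttr (0.64 ± 0.14) and Trf (0.19 ± 0.061), were higher, Trf at −0.017 with the marker covariates. Dbh lay at −0.14 with the marker covariates, S100b at −0.15 in limma-voom and Trf at 0.10 on the deposited log2 values, none of them past the threshold. Of the genes in this paragraph Tek (0.017), Cldn5 (−0.18), Tie1 (−0.055), Pdgfrb (0.014), Notch3 (0.053), Acta2 (0.13), Tnni2 (0.46), Lrrn4 (0.032), Msln (0.041), S100b (−0.42), Dbh (−0.30) and Trf (0.26) lost their calls with the trend on animal number. Some of these differences, such as those of S100b and Dbh, were larger in size with the trend, and others, such as those of Tek and Lrrn4, smaller. Of the lung epithelium markers 1 was in the table and 0 were abundant enough to test.

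Adjusted over the list alone, the counts changed for 12 lists. Those lower in females became 13 for the sarcomere, 8 for cardiac stress, 26 for nuclear-encoded oxidative phosphorylation, 12 for immediate early and heat shock genes, 3 for brown adipocyte and 1 for skeletal muscle genes. Those higher in females became 1 for cholesterol synthesis, 5 for the cell cycle, 2 for smooth muscle, 3 for macrophage, 0 for erythroid and 3 for Schwann and neuronal genes. Set against all other genes with limma's camera and an estimated correlation between genes, 0 of 33 lists passed, with 4 lists at an unadjusted p under 0.05. A preset correlation of 0.01 called 15. The smallest adjusted p with an estimated correlation was 0.134, shared by the fibroblast and the branched-chain amino acid lists. The other preset calls had an adjusted p with an estimated correlation of 0.359 for fatty acid oxidation and mitochondrially encoded genes, of 0.425 for nuclear-encoded oxidative phosphorylation, extracellular matrix, cardiac stress and glycolysis, and of 0.459 for sarcomere and T and NK cell genes. It was 0.573 for heat shock, 0.681 for adipocyte, 0.777 for glucocorticoid and 0.791 for interferon and B cell genes. In fry, which asks whether a list moves on balance one way and compares it with no other genes, 21 lists passed, and 1, the steroid list, passed in its test for changes in either direction. Median and mean had opposite signs for PPAR-alpha targets, cholesterol synthesis, clock, erythroid and brown adipocyte genes, and camera's direction went against both for the steroid and the integrated stress response lists.

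**Figure D3:**
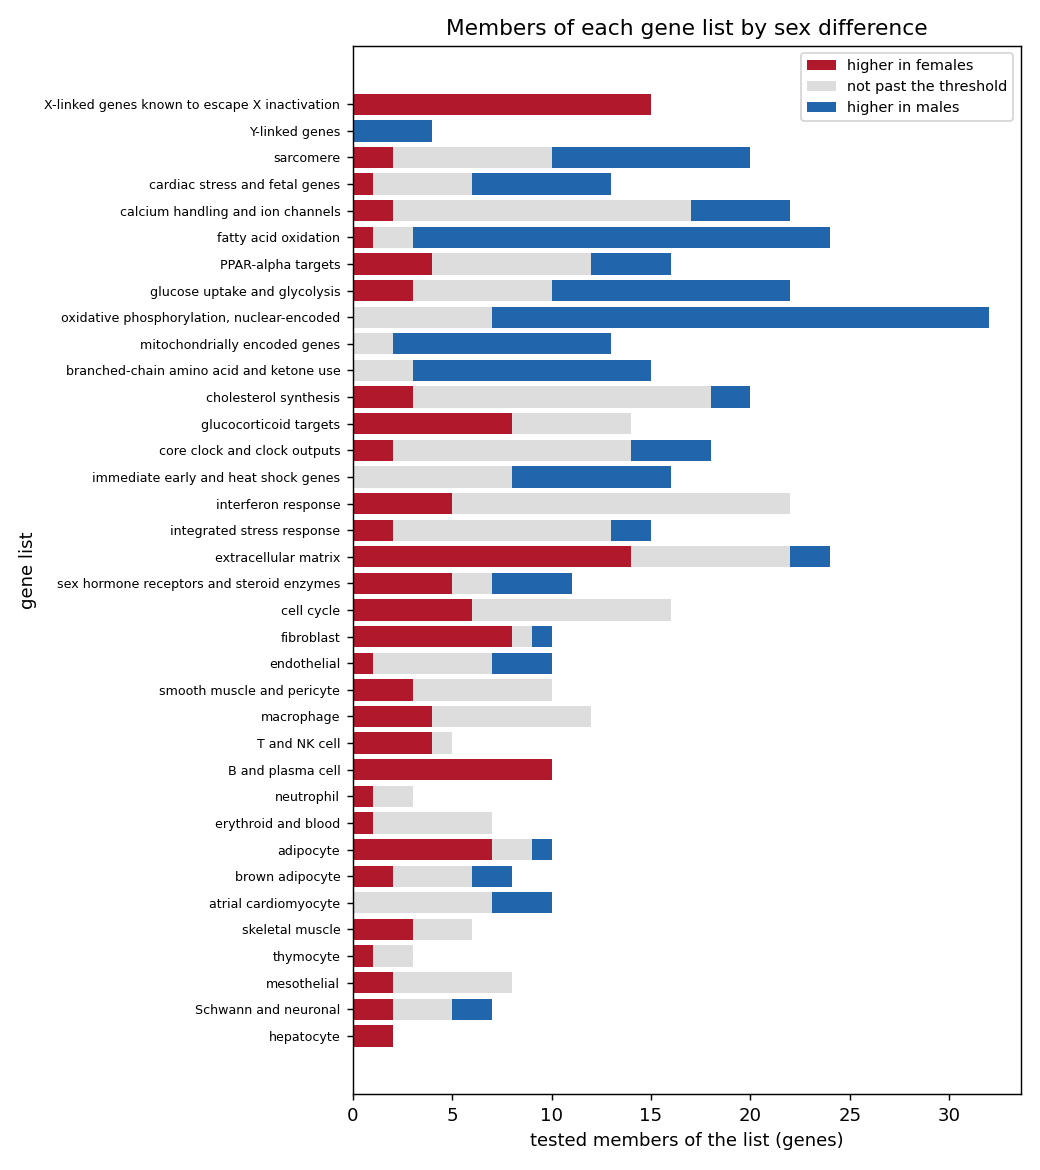
Number of tested members (horizontal axis, genes) of each gene list (vertical axis) that were higher in females (red), not past the threshold (gray) or higher in males (blue) in edgeR's test. All 15 escape genes and all 10 B and plasma cell markers were higher in females, and 25 of 32 nuclear-encoded oxidative phosphorylation genes were higher in males.

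Over the called autosomal genes, the log2 fold changes of 2 blocks correlated at r = 0.21 for blocks 1 and 3 and up to 0.79 for blocks 4 and 5. Among the genes chosen for having the same sign in all blocks, Col14a1 was higher in females by 0.74 to 0.96 on the log2 scale in the 5 blocks, and C7 lay between −2.39 and −1.93. Other genes depended on the block. The T cell transcription factor gene Tcf7 was higher in females by 4.78 in block 1, with −0.95, −0.49, −1.16 and 0.028 in the other blocks, and Cd4 by 3.90 in block 1, with −0.45 to 0.61 elsewhere. Top2a, which untangles DNA in dividing cells, was higher by 1.88 in block 1, with −0.33 to 0.35 elsewhere, and the leukocyte genes Ptprc by 1.47, Coro1a by 1.46 and Arhgap45 by 1.19. The chemokine gene Ccl25 was higher by 0.99 in block 1. In edgeR's interaction test 634 genes passed, of 2587 with an unadjusted p under 0.05, and limma on log2 CPM called 58. Blocks 1 to 5, each fitted alone, gave 8.41%, 6.58%, 1.68%, 7.22% and 7.25% of genes higher in females and 6.80%, 7.77%, 1.53%, 7.45% and 7.94% higher in males. Without 18 libraries high in thymocyte markers, 10 of them block 1 females, a choice made after seeing the data, 0.802% of genes passed the interaction test, and block 1 gave 1.59% and 1.57%.

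**Figure D4:**
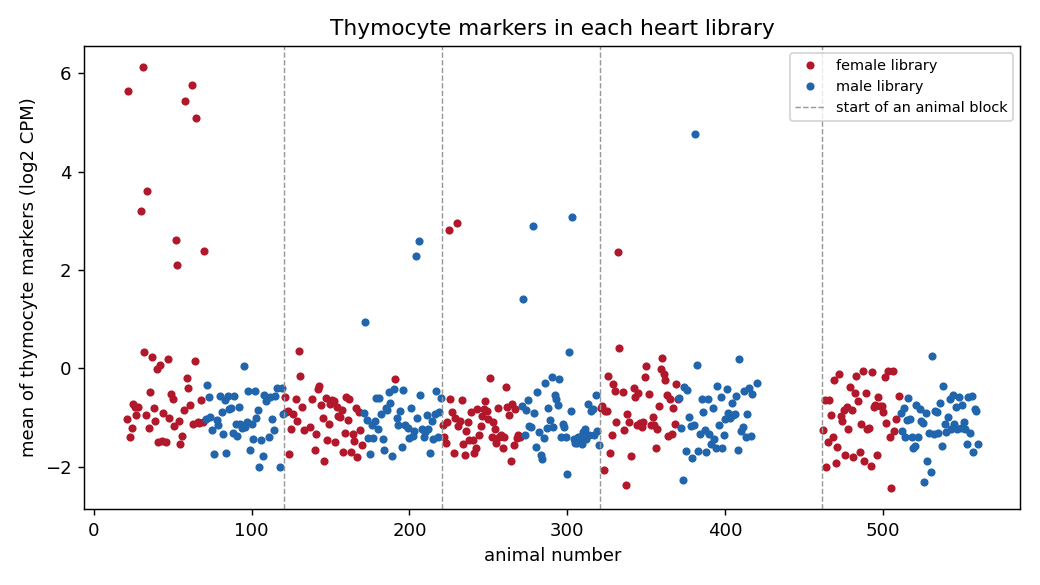
Mean of the 3 tested thymocyte markers, Cd4, Tcf7 and Arpp21 (vertical axis, log2 CPM), in each heart library by animal number (horizontal axis), with females in red, males in blue and dashed lines at the start of blocks 2 to 5. Of the 18 libraries more than 5 median absolute deviations above the median of their sex, 10 were block 1 females.

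Animal blocks also differed in level. Fosb, an immediate early transcription factor gene, had mean log2 CPM values of 0.35 ± 1.12 (SD, n = 95) and 0.68 ± 1.00 (n = 94) in blocks 1 and 2 and of 2.61 ± 1.66 (n = 100), 2.52 ± 1.87 (n = 95) and 2.28 ± 1.71 (n = 98) in blocks 3 to 5 (adjusted p = 2.2e-32 in edgeR's test). Mki67 was highest in block 1, at 2.57 ± 1.26, and lay between 1.99 and 2.14 elsewhere. The block 1 level was that of its females, at 16.7 CPM against 5.48 CPM in its males and 4.02 to 5.29 CPM in the sexes of the other blocks, and 10 block 1 females were among the 18 libraries high in thymocyte markers. In edgeR's test 2627 genes differed between blocks and 21 between library series, each with the other in the fit. Blocks 1 and 2 lay wholly in series 1 and blocks 4 and 5 in series 2. Only block 3 held both, with 9 male libraries in series 2, 41 in series 1 and its females all in series 1. Block and series are thus hardly told apart, and the 21 calls do not show that series matters little. Without the 18 libraries 1533 genes differed between blocks.

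Between animals of the same sex and block heart genes had a median residual SD of 0.289 on the log2 scale, or 0.159 on the deposited log2 values, with values of 0.129 and 0.926 at the 10th and 90th percentiles. Nuclear-encoded oxidative phosphorylation genes were the steadiest of the lists of at least 5 genes, with a median SD of 0.124, followed by endothelial markers at 0.170 and sarcomere and fatty acid oxidation genes near 0.174. B and plasma cell markers varied most, at 1.38, followed by adipocyte (1.30) and erythroid (1.26) markers. Within lists, Myh7 varied most among sarcomere genes (0.957), Acta1 among stress genes (1.08), Dbp among clock genes (1.20), Fosb among immediate early genes (1.51) and Ucp1, the uncoupling protein of brown fat, among brown adipocyte genes (2.58). Among abundant autosomal genes the widest spread was that of Rpl19-ps11 (SD 4.31), Hba-a1 (4.19) and Fabp3-ps1 (3.53). Pseudogenes made up 49 of the 100 genes with the widest spread against 1.12% of the 11176 such genes, and reads of a pseudogene and its parent can be split by the counting, so these values are uncertain. Sex took a median of 0.794% and block 1.11% of the variance per gene, each beyond the other and library series. What block shares with series is thus left out. Block had 4 degrees of freedom, more than sex, and takes up more variance by chance, so the 2 medians cannot be ranked. Over 10% of the variance was due to sex in 585 genes and to block in 42.

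Few genes varied more in 1 sex than in the other. Lvrn (residual SD 0.843 in females and 0.568 in males), Apoo (0.498 and 0.294), Ndufb11 (0.219 and 0.117), the citrate synthase gene Cs (0.118 and 0.0860) and Uba1 (0.0903 and 0.0625) were among 9 genes with the larger spread in females (17 on the deposited log2 values), 3 of these 5 being X-linked. Among 20 genes with the larger spread in males were Xist (0.759 and 1.08 in females and males), Ftx (0.258 and 0.410), Csf1, the macrophage growth factor gene (0.269 and 0.404), Reps2 (0.343 and 0.606) and the pseudogene Sms-ps (1.4999 and 2.94). Xist and the Y-linked genes lay near 0 counts in 1 sex, where log2 values depend on the prior count. These counts came from limma on absolute deviations, with 1442 genes at an unadjusted p under 0.05, and 12 of 16510 unchanged genes were called on simulated data, so single calls rest on their own p. For Lvrn the adjusted p was 1.5e-06 in limma and for Csf1 0.000325.

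The genes and lists compared were related across animals once sex, block and series had been removed, some rising together and some opposed. The clock gene Arntl and its output Dbp were opposed (Pearson r = −0.83, Spearman rho = −0.82), and Pdk4 and Angptl4, both PPAR targets, rose together (r = 0.66, rho = 0.66). The natriuretic peptide genes Nppa and Nppb had r = 0.35 and rho = 0.33, and the myosin genes Myh6 and Myh7 r = −0.23 and rho = −0.23. For the list means, adipocyte and brown adipocyte markers had r = 0.67 and rho = 0.66, PPAR-alpha targets and fatty acid oxidation r = 0.38 and rho = 0.35, and cardiac stress and extracellular matrix genes r = 0.31 and rho = 0.30. In females Xist and the other escape genes had r = 0.41 and rho = 0.39. These 8 relations had a two-sided permutation p of 1e-05 for both measures, the smallest that 100000 permutations can give, with a Benjamini-Hochberg adjusted value of 1.1e-05 over the 9 relations computed. The loosest was that of nuclear-encoded with mitochondrially encoded oxidative phosphorylation genes (r = 0.17, permutation p = 0.00025, adjusted 0.00025, and rho = 0.19, permutation p = 3e-05, adjusted 3e-05). The mitochondrially encoded mean includes mt-Co2, whose residual SD was 3.02 against a median of 0.327 in its list. That gene can weigh heavily in the mean, and the relation without it was not computed.

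Without the 2 animals farthest from the median of the x measure, r was −0.84 for Arntl and Dbp, 0.65 for Pdk4 and Angptl4, 0.32 for Nppa and Nppb, −0.24 for Myh6 and Myh7 and 0.66 for the adipocyte lists. It was 0.38 for PPAR-alpha targets, 0.31 for stress and matrix genes, 0.47 for Xist and 0.18 for the oxidative phosphorylation lists. Within the 10 combinations of sex and block, r ranged from −0.88 to −0.74 for Arntl and Dbp, from 0.49 to 0.79 for Pdk4 and Angptl4, from 0.12 to 0.59 for Nppa and Nppb and from −0.43 to −0.018 for Myh6 and Myh7. It ranged from 0.56 to 0.77 for the adipocyte lists, from 0.18 to 0.50 for PPAR-alpha targets and fatty acid oxidation, from 0.012 to 0.59 for stress and matrix genes and from 0.21 to 0.67 for Xist in the 5 blocks of females. The oxidative phosphorylation lists had the same sign in 9 of 10 combinations, with r from −0.022 to 0.35.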

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

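The thymus test, the criteria for the Xist libraries, the adipose tissue test and the removal of single libraries were chosen after the result was seen, and the reading of the B cell bound was changed after it. The genes of the next paragraph were picked out because their sex difference varied between animal blocks in edgeR's interaction test.

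Of 634 genes whose sex difference varied between blocks 28 were named genes. For T cell and thymocyte genes, all with their highest value in block 1 females, the adjusted p of edgeR's interaction test was 4.15e-25 for Tcf7, 2.07e-19 for Cd4, 3.83e-13 for Trac, 8.98e-13 for Cd3e, 2.55e-12 for Arpp21, 1.37e-08 for Thy1, 6.96e-07 for Cd2 and 0.00975 for Il7r. For the leukocyte and cell cycle genes with the same excess in block 1 it was 1.4e-11 for Top2a, 3.19e-11 for Ptprc and 1.63e-10 for Coro1a. In the same interaction test it was 2.05e-10 for Arhgap45, 6.54e-10 for Kif11, 1.97e-09 for P2ry10 and 5.51e-09 for Mki67. The chemokine gene Ccl25 also had this excess, with an adjusted p of 6.63e-11 in edgeR's interaction test. The B and plasma cell genes Cd79a (0.000163), Ms4a1 (0.000326) and Cd79b (0.000676) were higher in females of blocks 1, 4 and 5, with Cd79a at 1.21, 1.13 and 1.18, and Mzb1 had an adjusted p of 0.00781 in edgeR's test. Erythroid genes and the neutrophil gene S100a9 ran the other way, lower in block 1 females and higher in block 5 females, with −1.22 and 3.28 for Slc4a1 (adjusted p = 5.53e-12 in edgeR's test), −0.76 and 0.94 for Alas2 (1.25e-05), −0.67 and 0.60 for Hbb-bs (0.000885) and −0.70 and 1.82 for S100a9 (0.00226). Without the library of female DO497 of block 5, the highest in erythroid and neutrophil markers, the block 5 values were 1.67 for Slc4a1 (5.23e-05), 0.25 for Alas2 (0.0606), 0.10 for Hbb-bs (0.137) and 0.54 for S100a9 (0.392), so of these only Slc4a1 still passed the interaction test. Krt18 was higher in block 1 females by 1.103 (1.63e-06), Ttr by 1.71 (0.0339), Tnnt3 most in block 5 by 2.16 (0.0013), and Jpx ranged from 0.32 to 0.70 (0.0403). Ttr did not pass the interaction test without the library of female DO64, the highest in hepatocyte markers (0.92 in block 1, adjusted p = 0.516 in edgeR's test), nor Tnnt3 without that of female DO503, the highest in skeletal muscle markers (0.15 in block 5, 0.515).

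The first pattern weighed is the excess of lymphocyte and cell cycle genes in block 1 females. As scores, adipocyte (0.53 ± 0.21, SE) and skeletal muscle (0.30 ± 0.14) markers were also higher in these females. Neutrophil (0.18 ± 0.19) and macrophage (0.014 ± 0.064) markers lay within 1 SE of 0, and erythroid markers were lower (−0.61 ± 0.22). Thymus tissue carried with some hearts is a candidate explanation. Without the 18 libraries high in thymocyte markers, limma's interaction calls went from 58 to 1. Of 20 random removals of as many libraries per sex and block, 1 also left 1 (median 70). These removals were drawn from all libraries of a sex and block, so they could take out some of the 18 themselves. The count thus leaves thymus tissue open. The highest library, that of female 31, held 71.8 CPM of Cd4, 229.9 of Tcf7 and 27.7 of Ccl25. The thymocyte score rests on Cd4, Tcf7 and Arpp21 alone. As a score, T and NK cell markers were higher in block 1 females by 1.199 ± 0.31 (SE), about as much as the thymocyte markers. The thymocyte score thus cannot part thymocytes from other T cells. Blood left in the hearts is argued against by the erythroid genes, whose median in block 1 was −0.67, against 3.90 for the thymocyte genes. Tissue rich in B cells cannot be told apart: the B and plasma cell median of 1.21 lay under the bound set before the test, but that bound took its error from another scale, on which the difference was 1.04 ± 0.34 against 1.247 ± 0.33 for thymocytes (SE), and a biological difference between females of the blocks stays untested.

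The second pattern is Xist at the male level in the libraries of females DO153 and DO347. Both had a summed Y-linked count of 0, where a male library always had Y-linked reads. All female libraries together had a count of exactly 0 over the Y-linked genes. How reads were counted, and whether the labelled sex was used, is not given here. The 0 could thus follow from the label, and a mislabelled male stays open. For the 14 other escape genes 3 criteria were tried one after another with the values in view, and they disagreed, so an outcome is stated only where all 3 gave it: the score lay −4.33 SDs from the mean of the other females and 3.25 SDs from that of the males in animal DO153, which met 2 criteria for females and 1 for males, and −6.06 and 1.55 SDs in animal DO347, which met 2 and 3. A single X chromosome in all cells may account for animal DO347, and in animal DO153 neither it nor loss of Xist RNA with both X chromosomes kept can be told apart. No other biological explanation was tested.

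The third pattern is the difference in adipocyte genes, for which a larger share of adipose tissue in female libraries was weighed by entering the mean of the other adipocyte markers as a covariate, a mean that includes genes with a sex difference of their own. Of 8 adipocyte genes past the threshold 4 stayed past it in their direction, which lies on the bound of the test. By the rule as written, a result on the bound counted against a larger share of adipose tissue. With a margin around the bound, added after the result was seen, a larger share cannot be told apart. Cfd went from 1.19 ± 0.15 to 0.77 ± 0.10 (SE), Retn from 1.41 ± 0.13 to 1.1005 ± 0.087, Lipe from 0.14 ± 0.027 to 0.081 ± 0.025 and Lep from −0.62 ± 0.16 to −1.03 ± 0.14; Cidec went from 0.49 ± 0.12 to −0.029 ± 0.043, Adipoq to 0.0022 ± 0.050, Pnpla3 to 0.11 ± 0.059 and Plin1 from 0.28 ± 0.12 to −0.25 ± 0.043, past the threshold the other way (adjusted p = 1.6e-07 in limma). More adipose tissue alone is argued against for Lep, which was lower in females before any covariate. Lep was scarce, with a median of 0.281 CPM and 0 counts in 44 libraries, so this rests on low counts. The covariate did not take up the whole of the difference in Retn and Cfd. Sex itself, as a biological difference in the adipocytes, stays open and untested.

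Chance was weighed by 100 splits per result with the real one included, drawing sex at random over all libraries, or within the block for single blocks, and blocks at random within each sex. The real split alone gave as many genes, so 1 of 100, for the sex difference (3856 higher in females and 3421 in males, against at most 0 and 1 in the other splits), for at least 1.5-fold (39 and 40, against 0 and 0), and for blocks 1 to 5 (12.2%, 14.3%, 3.03%, 14.8% and 14.4% of genes, against at most 3, 1, 2, 1 and 1 genes). The same held for interaction (58 against 3), block (2201 against 1) and spread in females (9 against 1) and males (20 against 0). For lists with a preset correlation 3 of 100 splits gave as many as the real 15, the highest other 17, and with an estimated correlation all 100 gave at least the real 0, which says nothing.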

How the results depend on the processing

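The alternatives without high-thymocyte libraries, without 6 libraries high in other markers and with a trend on animal number were chosen after seeing the data. Of the named genes past the threshold 88 (52.7%) kept their direction and their side in every setting, and of 17 not past it 1 did (5.88%). Calls lost with the same sign numbered 66 with the trend on animal number, 31 with marker covariates, 10 without the high-thymocyte libraries, 6 without those high in other markers, 9 on the deposited log2 values and 7 with limma-voom. Genes called only elsewhere included Tcf7 (1.85 with sex alone), Hbb-bs (−0.26), Hba-a2 (−0.47), Alas2 (−0.26) and Cnn1 (−0.11), the last 4 with limma-voom, and S100a9 (0.63 with sex alone). Gene numbers below are percentages of the 16710 genes of the fit with all libraries, in every setting. All 9 relations kept both on the deposited log2 values and with no covariates removed. With the trend on animal number 7.002% of genes were higher in females and 7.95% in males, the median SE being 1.96 times as large because females are numbered before males, and 2321 of the 2498 calls were also called without it in the same direction. For genes higher in females by at least 1.5-fold the value was 0.0598% on the deposited log2 values, 0.880% without a filter, 0.126% with the stricter filter, 0.808% with sex alone, 0.162% with marker covariates and 0.688% with the trend, against 0.395%. For those higher in males it was 0.0658% on the deposited log2 values and 0.114% with the stricter filter, against 0.263%. The deposited log2 values are on another scale and the stricter filter tested fewer genes. Otherwise the cause was not tested. Interaction calls were 1.80% (against 3.79%) with the stricter filter, 0.946% with limma-voom, 1.26% on the deposited log2 values and 0.802% without the high-thymocyte libraries, where blocks gave 9.17% and block 1 gave 1.59% and 1.57%. Spread on the deposited log2 values gave 0.102% in females and a median SD of 0.159, on their own scale, the cause not being tested. A preset correlation of 0.01 gave 15 lists. Their estimated correlations, from 0.16 for cardiac stress to 0.72 for B and plasma cell genes, lay far above that preset.

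Signs turned, the cause not being tested, as follows. With marker covariates they turned for genes including Pck1 (−0.013), Ptprc (−0.024), S100a9 (−0.099), Csf3r (−0.11), Adipoq (−0.0058), Elovl3 (−0.27), Arpp21 (−0.15), Tcf7 (−0.055), Krt18 (−0.10), Trf (−0.017) and Nppa (0.032). Without the high-thymocyte libraries they turned for Top2a (−0.025), Kif11 (−0.0027), Csf3r (−0.0044), Arpp21 (−0.13) and Krt18 (−0.015), and without those high in other markers for S100a9 (−0.0019). With the trend they turned for Sqle (−0.017), Hbb-bs (0.27), Hba-a2 (0.31), Alas2 (0.40), Elovl3 (−0.19), Arpp21 (−0.045), Tcf7 (−0.25), Upk3b (−0.0042), Arntl (−0.066) and Angptl4 (0.013). Slc4a1 (−0.015) and Dbp (−0.15) turned with limma-voom, Dbp (−0.061) on the deposited log2 values and Alas2 (0.018) with sex alone. Leaving out libraries under 50% of the median depth removed 0 libraries and gave no value. No paired analysis was possible because no animal number occurs in both sexes. With 16510 of 16710 simulated genes unchanged, a change of 1.1-fold was found for 38 of 50 genes. In the real data 7299 genes passed, which makes the adjusted threshold less strict, and the median called autosomal difference was 1.06-fold. The simulated share thus does not tell how often small real differences are missed.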

Other observations

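The values in this part were all singled out after they were seen, and none was tested. The mitochondrially encoded gene mt-Co2, a subunit of cytochrome c oxidase, ran from 4.90 to 6210 CPM between hearts, with a mean of 2058 ± 1180 (SD), a coefficient of variation of 57.3%. The sum of mt-Co2 and mt-Atp6 varied by 26.9%, and mt-Atp6 was the gene picked because it moved most against mt-Co2. Iigp1, an interferon-induced GTPase gene, had the widest spread of the interferon list (SD 2.14), and Bmp10 of the atrial list (SD 1.499). Ucp1 ran from 0.116 CPM at the 10th percentile to 18.4 CPM at the 90th, and Acta1 from 121.9 to 942.1 CPM.

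Besides these, the female library of animal 38 of block 1, held 90.7 CPM of Xist against a median of 359.9 CPM in the other females. In it the escape genes Shroom4, Ddx3x and Kdm6a, which start at bases 6399854, 13280970 and 18162575 of the X chromosome on GRCm38, lay at 14.9, 134.3 and 15.7 CPM, below the male medians of 30.8, 180.3 and 18.7 CPM. Eif2s3x, which starts at base 94188707, lay at 129.4 CPM, and Pbdc1, at base 105079756, at 7.66 CPM, with medians of 148.5 and 7.22 CPM in the other females. Utp14a, at base 48256862, lay at 16.7 CPM against 15.99 CPM in the other females, whereas Kdm5c, at base 152233020, lay at 63.04 CPM, between the medians of 77.03 CPM in the other females and 49.6 CPM in the males, so the levels did not part cleanly by position. Its escape score, the mean of 14 genes each in SDs of that gene among the females other than DO153 and DO347, was −2.15, the lowest of all females. The library of animal 38 widened the female range used in judging animals DO153 and DO347, whose scores on this scale were −1.44 and −2.02. The score itself had an SD of 0.333 in the other females, and the SDs given above for DO153 and DO347 are not on this scale.

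Several kinds of marker showed libraries far from the rest. Skeletal muscle markers lay more than 5 median absolute deviations above the median in 4 libraries, the highest that of female DO503 at 11.2. Hepatocyte markers did so in 1 library, that of female 64 at 6.44, and erythroid and neutrophil markers in the library of female DO497, at 5.06 and 5.75. Adipocyte, atrial, mesothelial and macrophage markers did so in 0 libraries.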
